A study of Homo sapiens with 8 samples.

How the data were processed

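RNA of cultured primary human keratinocytes was hybridized to Affymetrix HG-U133 Plus 2.0 arrays, on which a set of short probes near the 3' end stands for each transcript. There were 8 arrays in 4 groups of 2, all from cells harvested 5 days after knockdown: controls and EXOSC9 knockdown in a first set, and controls and EXOSC9 plus GRHL3 knockdown in a second set. Groups were taken from the sample titles. The labels call the duplicates biological replicates and say nothing on donors, so p-values measure the spread between these cultures.

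The deposited values were made by the authors with RMA, per the submitters' processing notes, which adjusts background, equalises the distributions of arrays and summarises probes to 1 value per probe set. The version and whether both sets were processed in 1 run are not given in the sources used here. The deposited values were taken as log2 from their range of 2.14 to 14.5, as no header states the scale. Arrays of the same set shared between 295 and 567 identical values in pairs and no value was shared between sets, and the second controls differed from the first by a median of -0.11, so each knockdown was tested only against the controls of its own set. RMA gives a value to every probe set whether or not the transcript is detected, and it compresses changes of dim ones.

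The table held 54675 probe sets, of which 62 controls were left out. In the platform annotation 41097 probe sets had 1 gene symbol, 1801 several and 11721 none, and 41043 symbols were updated through their Entrez identifier with RefSeq gene tables. No reference genome was used, and no coordinates are given. For each gene the probe set with the highest mean over the 8 arrays was kept among those with 1 symbol, which left 19775 genes, 10523 of them with several probe sets. In 40 genes of the EXOSC9 comparison and 88 of the double comparison probe sets of a gene passed the test in opposite directions.

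Each gene was fitted with 4 group means in limma 3.58.1 (R 4.3.3), with lmFit and eBayes on all 8 arrays, which left 4 residual degrees of freedom and 2.75 prior ones. The contrasts were each knockdown against its controls, the difference of these 2 changes, and the controls of the sets against each other. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The fits were tested on simulated values for 19775 genes, with the mean and spread of each gene taken from a fit to the data. Changes of 0.5, 1 and 2 log2 units, given to 67, 67 and 66 genes, were recovered in 86.6%, 100% and 100% of cases for the EXOSC9 comparison. The shares were 83.6%, 98.5% and 100% for the double and 44.8%, 95.5% and 100% for the difference. In the same order, 5.91%, 3.59% and 5.33% of the calls were on unchanged genes. The simulated arrays were independent, so these shares need not hold for control groups that deviate together. Far fewer genes were changed than were called in the knockdown comparisons of the data (3059 and 4408). The shares depend on that number, so they need not hold for these comparisons. Groups of 2 are too small for a test of outlying arrays or for counting other splits of the samples.

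Because the control arrays of both sets deviated together, the fits were repeated with each control array counted once, as 6 arrays with 3 residual degrees of freedom. The control levels of each gene were averaged over the sets and the double knockdown was moved with its controls, so fold changes were the same. The size of this move was taken as known, so its error is missing from the SE of the difference. The covariance from shared controls was estimated in 100 simulated draws of unchanged groups.

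In all, 19 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, with an estimated correlation and with fry as alternatives. They covered cornified envelope and late differentiation, spinous differentiation, epidermal lipid barrier, differentiation transcription factors, basal and progenitor genes, cell cycle and DNA replication, RNA exosome subunits and cofactors, AU-rich element and immediate early mRNAs, inflammatory cytokines, interferon response, p53 targets and senescence, unfolded protein and amino acid response, cholesterol synthesis, histones, snoRNA hosts, matrix and wound genes, and markers of fibroblasts, melanocytes, and immune and endothelial cells. Genes were named by a rule: both targeted genes, the 10 largest rises and falls among the called genes of each knockdown contrast and of the difference (5 for the controls), and up to 4 called members of each list, or the 2 brightest where none was called. The groups, the tests, the lists, this rule and most alternatives were chosen before the data were examined. Single genes outside the rule are said to have been looked up afterwards. A weaker camera p with the estimated correlation need not come from correlation between genes. It also appeared where the estimate lay below the preset 0.01.

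Alternatives covered centring and quantile normalization over all arrays, the mean of a gene's probe sets, every probe set, genes above the median level, a variance prior with a trend or a robust one, only the arrays of a set, pooled controls, thresholds with at least a 2-fold change, a replicate block, leaving out each array, and a direct contrast of both knockdowns. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.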

Results

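Primary human keratinocytes, the main cell type of the epidermis, were grown in a medium that keeps them dividing and undifferentiated, and their mRNA was measured on 8 Affymetrix whole-genome arrays 5 days after knockdown. There were 4 groups with 2 arrays each. In a first set of 4 arrays, cells that carried a control shRNA and a control siRNA were compared with cells that carried an EXOSC9 shRNA and the control siRNA. In the second set, controls of the same description were compared with cells that carried the EXOSC9 shRNA and a GRHL3 siRNA. EXOSC9 encodes a core subunit of the RNA exosome, the complex that degrades and trims RNA from the 3' end, and GRHL3 encodes a grainyhead-like transcription factor needed for the epidermal barrier. The study asked whether the exosome holds back differentiation in progenitor cells, and whether GRHL3 is needed for what follows when EXOSC9 is lost. Levels are log2 values, changes are differences of log2 means with the SE of the limma fit, and n = 2 arrays in each group unless stated. The array medians lay between 5.49 and 5.53 in the first set and between 5.33 and 5.35 in the second. For arrays it is their number that limits the precision, and the median SE of a knockdown change was 0.067.

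EXOSC9 mRNA was lower in every knockdown array. Its level was 9.67 ± 0.01 (SD, n = 2) in the first controls and 7.24 ± 0.10 after EXOSC9 knockdown, a fall of 5.41-fold (log2 change -2.43, SE 0.06, limma adjusted p = 9.3e-06). In the second set it was 9.62 ± 0.02 in controls and 7.08 ± 0.04 in the double knockdown, 5.80-fold lower (log2 change -2.54, SE 0.06, limma adjusted p = 1.4e-05). GRHL3 rose on EXOSC9 knockdown alone, from 6.37 ± 0.08 to 8.28 ± 0.16 (log2 change 1.91, SE 0.09, limma adjusted p = 0.00013). With the GRHL3 siRNA it stood at 6.09 ± 0.02 against 6.14 ± 0.10 in its controls (log2 difference -0.05, SE 0.09, limma adjusted p = 0.78). The 2 responses of GRHL3 differed by -1.96 (SE 0.13, limma adjusted p = 0.0018). Against its own controls the level with the GRHL3 siRNA did not pass the test for a fall. What these arrays show with the siRNA is the absence of the rise.

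**Figure D1:**
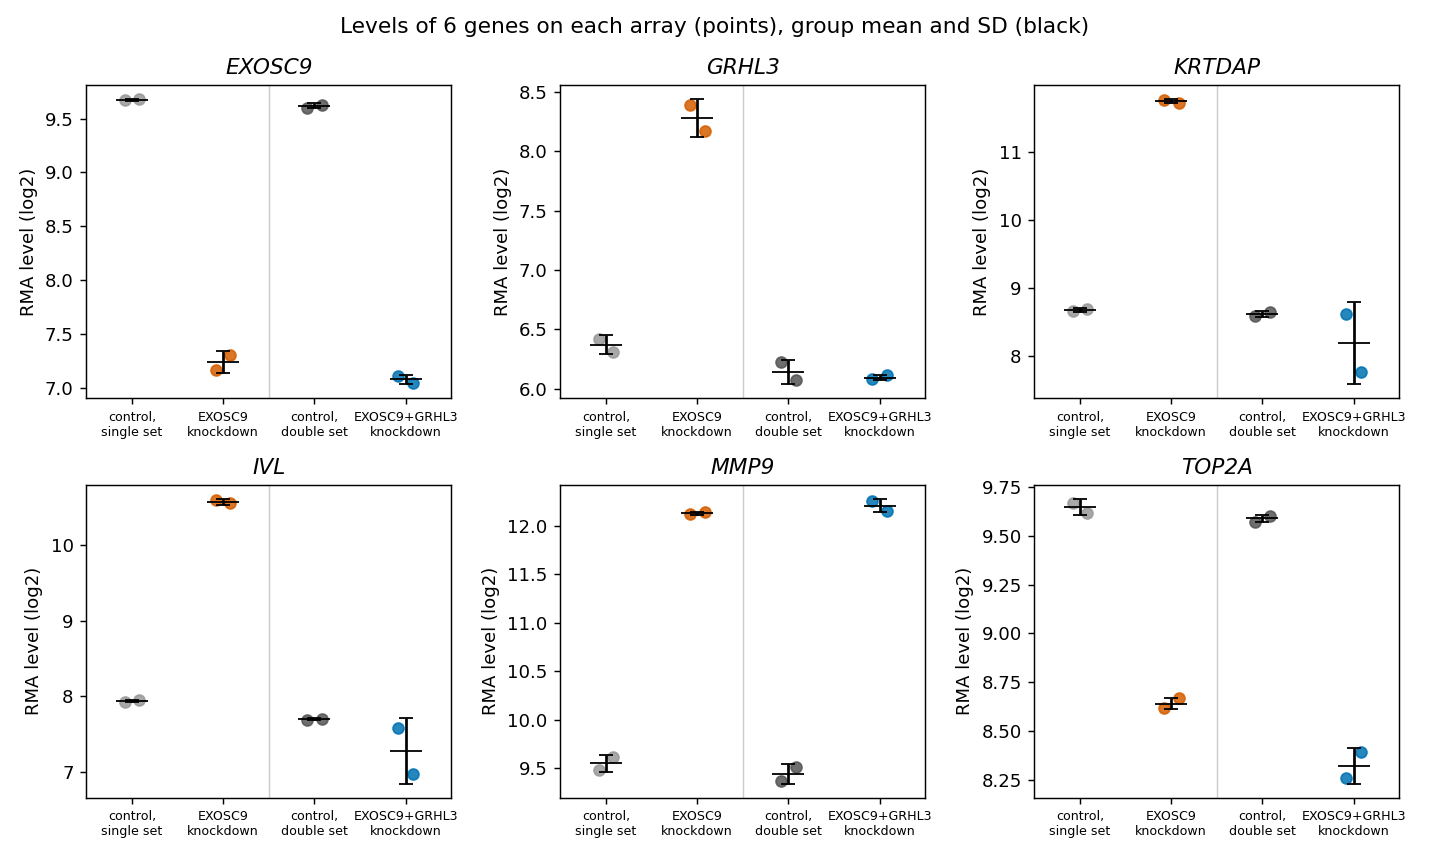
Levels (RMA, log2, y axis) of EXOSC9, GRHL3, KRTDAP, IVL, MMP9 and TOP2A in the 4 groups (x axis), with 1 point per array and black bars for the group mean and SD (n = 2). EXOSC9 was lower in both knockdowns, GRHL3, KRTDAP and IVL were higher in the EXOSC9 knockdown alone, and MMP9 and TOP2A moved in the same direction in both knockdowns.

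The first comparison asked what happened when EXOSC9 alone was depleted. Genes of the outer, differentiated layers of the epidermis rose steeply and genes of cell division fell. The largest rise was that of ZNF750, a transcription factor of terminal differentiation, at 3.55 (SE 0.30, limma adjusted p = 0.00055), followed by the amino acid transporter SLC6A14 at 3.52 and the homeodomain protein HOPX at 3.15. KRTDAP, a secreted protein of suprabasal keratinocytes, rose by 3.06, the calcium-binding protein S100A8 by 3.03, the protease inhibitor SLPI by 2.88, and the suprabasal proteins SBSN and CRCT1 by 2.80 and 2.77. SPINK6, an inhibitor of kallikreins, rose by 2.68 and the skin chemokine CCL27 by 2.63. After EXOSC9 itself, the largest falls were those of the chloride channel ANO1 (-1.54), the cell cycle transcription factor E2F8 (-1.40), the replication factor MCM10 (-1.21), MYBL1 (-1.19), POGLUT3 (-1.17), CEP55 (-1.12), the cohesin acetyltransferase ESCO2 (-1.12), cytoglobin CYGB (-1.10) and the origin recognition subunit ORC1 (-1.08). Each of these passed limma with an adjusted p of 0.00067 or less.

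Of 19775 genes tested in the first comparison, 1341 rose and 1718 fell, with a median absolute log2 change of 0.34. Rises of at least 2-fold outnumbered falls of that size, 121 against 23. With 2 arrays per group the counts depended on each array: without 1 of the 4 arrays of the comparison, whichever it was, 600 to 674 genes rose and 726 to 901 fell. With the control arrays of both sets pooled, 1635 rose and 1106 fell. ZNF750, IL33, DSG1 and SLC6A14 had control levels of 3.71, 3.69, 3.48 and 3.35, and like that of SDR9C7 these lay below the lower quartiles of the arrays of the first set, the lowest of which was 4.02. The values carry no detection call, so the sizes and ranks of their rises are uncertain. Of 55 named and called genes with several probe sets, 35 had one that changed by less than 50% of the value given, 13 of them in the opposite direction, with changes between 0.02 and 3.15 for HOPX, 0.60 and 3.03 for S100A8, 0.56 and 2.16 for GRHL1, -1.54 and -0.18 for ANO1, -1.19 and 0.06 for MYBL1, -1.12 and -0.04 for ESCO2 and -1.10 and 0.01 for CYGB.

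Among the gene lists, the cornified envelope and late differentiation list moved furthest upward. Of its 45 measured members 30 rose and none fell, with a median change of 0.72, and 33 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.94e-21, and adjusted p = 0.00397 with an estimated correlation). KRTDAP, SBSN, CRCT1 and LCE3D (2.63) led it, and the envelope precursor involucrin (IVL) rose by 2.63. Of 35 spinous differentiation genes 25 rose and none fell, with a median of 0.47 (26 and 1 adjusted over the list alone, camera adjusted p = 2.94e-21, and adjusted p = 0.0105 with an estimated correlation). S100A8, the desmosomal cadherin DSG1 (2.54), S100A9 (2.37) and S100P (2.00) led that list. The keratins KRT1 and KRT10, looked up after the values were seen, did not pass the test, at -0.17 (SE 0.06, limma adjusted p = 0.13) and 0.03 (SE 0.06, limma adjusted p = 0.80). Of 28 differentiation transcription factors 12 rose and 2 fell (median 0.24, camera adjusted p = 3.71e-06, and adjusted p = 0.127 with an estimated correlation), led by ZNF750, HOPX, GRHL1 (2.16) and GRHL3. Adjusted over the list alone, the epidermal lipid barrier list had 8 rises and 1 fall among 28 members, against 7 and 1 over all genes (median 0.10, camera adjusted p = 0.0152, and adjusted p = 0.127 with an estimated correlation), with the lipid transporter ABCA12 at 1.83 and SDR9C7 at 1.41.

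Cell division genes fell almost without exception. Of 52 cell cycle and DNA replication genes 50 fell and none rose, and 51 fell when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 4.15e-44, and adjusted p = 0.00397 with an estimated correlation). Topoisomerase TOP2A fell by 1.00 on the log2 scale and the replication factor GINS2 by 0.98, with other probe sets at up to -0.19 and 0.11. Basal and progenitor genes went both ways, with 6 rises and 10 falls among 34, a median of 0.01 and a mean of -0.01 (camera adjusted p = 0.832, direction down). ID3 rose by 1.10 and the basal keratin KRT15 by 0.94, while MCAM (-1.04, with another probe set at -0.01) and UHRF1 (-0.90) fell.

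Smaller shifts appeared in other lists of the first comparison. Of 30 p53 target and senescence genes 14 rose and 3 fell (median 0.19, camera adjusted p = 0.000304, and adjusted p = 0.0542 with an estimated correlation), with IGFBP3 at 0.77, TP53INP1 at 0.70 (-0.03 by another probe set), the cyclin kinase inhibitor CDKN2B at 0.66 and lamin LMNB1 at -0.90. Of 42 immediate early and AU-rich element genes 14 rose and 4 fell (median 0.10, camera adjusted p = 0.000662, and adjusted p = 0.127 with an estimated correlation), with PTGS2 at 1.02, EGR1 at 0.85 and DUSP1 at 0.76. Of 10 histone genes 7 rose (median 0.42, camera adjusted p = 3.43e-06, and adjusted p = 0.111 with an estimated correlation), led by H2BC21 at 1.17. Of 14 snoRNA host and processed noncoding RNA genes 4 rose, among them DANCR at 0.48 (median 0.14, camera adjusted p = 0.00749, and adjusted p = 0.119 with an estimated correlation). Of 53 interferon response genes 15 fell and 6 rose (median -0.09, camera adjusted p = 0.0041, and adjusted p = 0.219 with an estimated correlation), with CMPK2 and EPSTI1 each at -0.55. Of 21 cholesterol synthesis genes 8 fell and none rose (median -0.12, camera adjusted p = 0.00186, and adjusted p = 0.127 with an estimated correlation), with STARD4 at -0.45. Of 31 matrix, wound and mesenchymal-like genes 13 fell and 4 rose (median -0.02, camera adjusted p = 0.0343, and adjusted p = 0.127 with an estimated correlation). That call was lost without replicate 1 of the EXOSC9 knockdown (adjusted p = 0.0548), and the list held the gelatinase MMP9 at 2.58, the wound keratin KRT16 at 1.57, TGFBI at -0.85 and EPCAM at -0.82.

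Adjusted over the list alone, the members that rose and fell numbered 16 and 4 for the p53 list, 17 and 4 for immediate early genes, 8 and 0 for histones, 6 and 0 for snoRNA hosts, 7 and 21 for interferon genes, 1 and 9 for cholesterol genes, 4 and 13 for matrix genes, 14 and 2 for transcription factors and 7 and 10 for basal genes. They numbered 15 and 13 for cytokines, 7 and 12 for unfolded protein response genes, 2 and 6 for exosome genes and 3 and 2 for fibroblast markers. The remaining lists did not pass camera. Inflammatory cytokines split, with 14 rises and 10 falls among 39 (median 0.00, camera adjusted p = 0.187), and IL33 (2.52), the interleukin antagonist IL36RN (1.78) and IL36G (1.52) rose. The 33 unfolded protein and amino acid response genes had 7 rises and 9 falls (median 0.01 and mean -0.04, camera adjusted p = 0.591), with the chaperone HSP90B1 at -0.78 and PDIA4 at -0.66. The 29 RNA exosome subunits and cofactors had 2 rises and 6 falls (median -0.04, camera adjusted p = 0.094), in which ZFC3H1 rose by 0.75 and EXOSC6 by 0.36, and DIS3L fell by 0.64. Other named genes of the lists were called with all arrays but not without 1 to 4 of them in turn. Among them were SGPP2 (0.83) and ALOX12B (0.78) of the lipid barrier, EGR3 (0.90) of the immediate early genes, CHAC1 (0.56) of the unfolded protein response and H1-2 (0.67) of the histones. Further ones were MEG3 (0.59), SCARNA2 (0.58) and EPB41L4A-AS1 (0.20) of the snoRNA hosts, and LSS (-0.27) and NSDHL (-0.24) of cholesterol synthesis. CALML3, CCN1, CXCL5, EBP, EXOSC2, FOS, HMGCS1, IFI44L, KLF4 and MAF lost their calls in the same way. Few markers of other cell types passed. Fibroblast markers had 3 rises and 2 falls among 19 (camera adjusted p = 0.845). The rises were those of POSTN (0.54), DCN (0.39) and COL5A2 (0.29) and the falls those of THY1 (-0.41) and TWIST2 (-0.26). All 5 calls were lost without 1 or another array. Those of POSTN (adjusted p between 0.062 and 0.11) and DCN (0.07 to 0.081) were lost without replicate 2 of the controls or either knockdown array. Those of COL5A2 (0.053 to 0.089), THY1 (0.063 to 0.12) and TWIST2 (0.056 to 0.11) were lost without any of the 4. None of 14 melanocyte or 21 immune and endothelial markers passed limma (camera adjusted p = 0.994 and 0.768), and at an unadjusted p under 0.05 there were 0 rises and 1 fall among the first and 1 rise and 0 falls among the second, with SOX10 at 0.03 and ENG at -0.02.

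The second comparison asked what the cells did when they carried the GRHL3 siRNA together with the EXOSC9 shRNA. Cell division genes fell as they had before, but 31 of the 45 cornified envelope genes were not called in either direction. The largest rises were those of CCL27 at 4.15 (SE 0.09, limma adjusted p = 1.4e-05), MMP9 at 2.77, the growth factor BMP6 at 2.53, periostin (POSTN) at 2.37 and ZNF750 at 2.18. The control level of ZNF750 was 3.42, below the lowest lower quartile of these arrays (3.88), so the size and rank of its rise are uncertain. The antisense transcript ZEB1-AS1 rose by 2.13, PCF11, a factor of mRNA 3' end formation, by 2.12, TIGD1 by 2.01, DSP-AS1 by 1.90 and SPINK6 by 1.88. After EXOSC9 the largest falls were those of the gap junction protein GJA5 (-2.48), the neutrophil chemokines CXCL5 (-1.87) and CXCL3 (-1.79), the collagen COL8A1 (-1.80), AGR2 (-1.76), the TEAD cofactor VGLL1 (-1.70), E2F8 (-1.61), CCN2 (-1.57) and CYGB (-1.56). Each passed limma with an adjusted p of 0.0029 or less.

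In the second comparison 2294 genes rose and 2114 fell, of which 94 rose and 113 fell at least 2-fold. Without replicate 1 or replicate 2 of its controls the counts dropped to 1433 and 1187 rises and to 1236 and 1198 falls. With only the 4 arrays of its own set in the fit, 1480 rose and 1372 fell, and with the control arrays of both sets pooled 1577 rose and 2558 fell. Of 59 named and called genes with several probe sets, 41 had one that changed by less than 50% of the value given, 19 of them in the opposite direction, with changes between 0.04 and 2.53 for BMP6, -0.29 and 2.37 for POSTN, 0.11 and 2.12 for PCF11 and -0.16 and 1.73 for MAF. Among the falls they lay between -2.48 and 0.01 for GJA5, -1.80 and 0.11 for COL8A1, -1.87 and -0.21 for CXCL5, -1.76 and -0.31 for AGR2 and -1.70 and -0.02 for VGLL1.

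Of the 45 cornified envelope genes 6 rose and 8 fell in the double knockdown, with a median of -0.05 and a mean of 0.00 (7 and 11 adjusted over the list alone, camera adjusted p = 0.797). Members that rose were SPRR2B (1.41), KLK11 (0.95), SPRR1B (0.82) and, by the brighter of its 2 probe sets, SPRR3 (1.41, against -0.51 by the other), while IVL stood at -0.42 (SE 0.17, limma adjusted p = 0.14) and KRTDAP at -0.43 (SE 0.23, limma adjusted p = 0.26). Spinous genes rose in part, 13 up and 2 down of 35, with a median of 0.18 (16 and 3 adjusted over the list alone, camera adjusted p = 0.000115, and adjusted p = 0.143 with an estimated correlation), among them the tight junction protein CLDN1 (1.13), DSC2 (0.78), GJB6 (0.71) and CALML3 (0.67). Differentiation transcription factors had 11 rises and 3 falls (11 and 4 adjusted over the list alone, median 0.12, camera adjusted p = 0.0107, and adjusted p = 0.409 with an estimated correlation), with MAF at 1.73 and KLF4 at 1.03 beside ZNF750. Lipid barrier genes had 4 rises and 4 falls (4 and 4 adjusted over the list alone, median 0.00, camera adjusted p = 0.797), with ABCA12 at 1.47 and ELOVL7 at -0.83. Of 52 cell cycle genes 51 fell, also when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 4.96e-44, and adjusted p = 0.00797 with an estimated correlation), among them AURKB (-1.38), KIF23 (-1.30) and MCM10 (-1.28).

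Of 21 cholesterol synthesis genes 16 fell and none rose in the double knockdown, 17 when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 7.41e-10, and adjusted p = 0.0337 with an estimated correlation), led by ACAT2 (-0.74), EBP (-0.72) and HMGCS1 (-0.70). Of 30 p53 target and senescence genes 21 rose and 3 fell (22 and 3 adjusted over the list alone, median 0.26, camera adjusted p = 2.28e-06, and adjusted p = 0.0337 with an estimated correlation), with TP53INP1 at 1.14 and CDKN2B at 0.83. Of 53 interferon genes 19 rose and 4 fell (21 and 4 adjusted over the list alone, median 0.11, camera adjusted p = 0.000254, and adjusted p = 0.266 with an estimated correlation), among them RSAD2 (1.17), ISG20 (0.94) and IFI44L (0.85). Of 42 immediate early and AU-rich element genes 16 rose and 6 fell (18 and 7 adjusted over the list alone, median 0.11, camera adjusted p = 0.0179, and adjusted p = 0.353 with an estimated correlation), with FOS at 0.82, HBEGF at 0.81 and CCN1 at -1.02. That call was lost without replicate 1 of the double knockdown (adjusted p = 0.0645).

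The other lists did not pass camera in the double knockdown. Basal and progenitor genes had 10 rises and 10 falls (median 0.03, camera adjusted p = 0.797), with KRT15 at 1.74 and MCAM at -1.25. Histone genes had 1 rise and 4 falls (median -0.14, camera adjusted p = 0.236), with H2BC21 at -0.46. The snoRNA host list had 4 rises and no falls (median 0.11, camera adjusted p = 0.0679), and passed without replicate 2 of the controls (adjusted p = 0.0393) or replicate 2 of the double knockdown (adjusted p = 0.0482). Cytokines had 13 rises and 10 falls (median 0.02, camera adjusted p = 0.667). Unfolded protein response genes had 13 rises and 11 falls (median 0.11 and mean -0.01, camera adjusted p = 0.667), with HSP90B1 at -1.24. Exosome genes had 3 rises and 7 falls (median -0.06, camera adjusted p = 0.196). Matrix and wound genes had 8 rises and 7 falls (median -0.03 and mean 0.05, camera adjusted p = 0.672), with MMP10 at 1.40 and EPCAM at -1.24. Fibroblast markers had 1 rise, that of POSTN (2.37), and 3 falls, those of THY1 (-0.66), MFAP5 (-0.37) and TWIST2 (-0.31), with a camera adjusted p of 0.531. None of the melanocyte or the immune and endothelial markers passed limma (camera adjusted p = 0.862 and 0.412), and at an unadjusted p under 0.05 there were 1 rise and 1 fall among the first and 0 and 0 among the second. Adjusted over the list alone, the rises and falls numbered 10 and 12 for basal genes, 1 and 5 for histones, 4 and 0 for snoRNA hosts, 14 and 11 for cytokines, 15 and 11 for unfolded protein response genes, 4 and 8 for exosome genes, 9 and 10 for matrix genes and 1 and 3 for fibroblast markers. Named genes of the lists called with all arrays but not without 1 to 4 of them in turn included RORA (0.79), SGPP2 (0.54), MEG3 (0.52), STS (0.50), SCARNA2 (0.47), H1-2 (0.43), EPB41L4A-AS1 (0.22), H2AC6 (-0.29) and H2BC4 (-0.88). CRCT1, SBSN, LCE3D and PI3 of the cornified envelope list lost their calls in the same way. So did EGR3 of the immediate early genes, EPSTI1 and SP110 of the interferon genes and NSDHL of cholesterol synthesis.

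**Figure D2:**
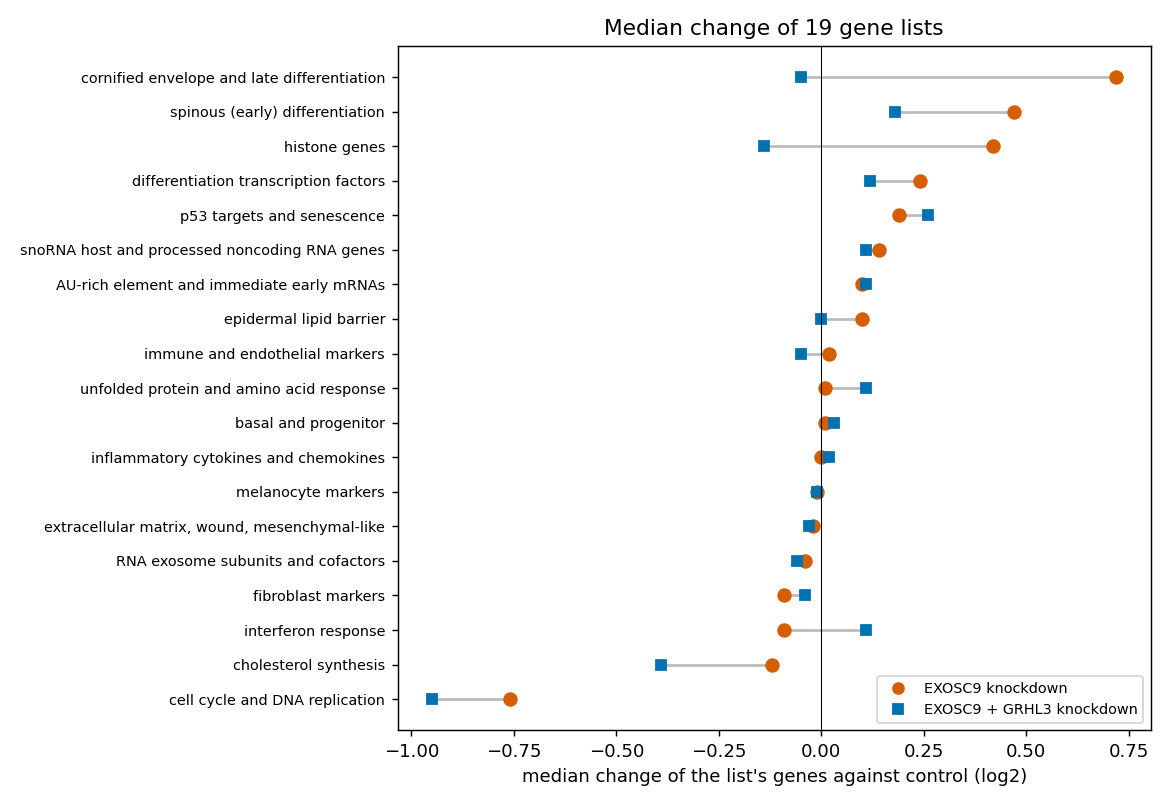
Median change of the members of 19 gene lists against their own controls (x axis, log2), for the EXOSC9 knockdown (orange circles) and the double knockdown (blue squares), with a grey line joining both values of a list. The cornified envelope list went from 0.72 to -0.05, and the cell cycle list from -0.76 to -0.95.

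The difference between the responses asked which genes changed differently in the double and the EXOSC9 knockdown, each against its own controls. No group held the GRHL3 siRNA without the EXOSC9 shRNA. An effect that this siRNA has by itself therefore cannot be told from a changed response to EXOSC9 loss. Late differentiation genes made up most of the largest differences, all lower in the double knockdown than in the EXOSC9 knockdown. The response of KRTDAP differed by -3.49 (SE 0.33, limma adjusted p = 0.0069), and those of SLC6A14 by -3.47, CRCT1 by -3.34, the late envelope protein LCE3D by -3.30, SBSN by -3.25, the elastase inhibitor PI3 by -3.24, IVL by -3.05, HOPX by -2.91, the chloride channel protein CLIC3 by -2.89 and the protease inhibitor SERPINB3 by -2.80. SLC6A14 had a level of 3.35 in the first controls, below the lowest lower quartile of that set (4.02), so the size and rank of its difference are uncertain. CLIC3 rose in one knockdown (1.46) and fell in the other (-1.43). Higher in the double knockdown were the responses of POSTN (1.83), osteopontin SPP1 (1.71), LOC100130331 (1.57), CCL27 (1.52), SLITRK6 (1.46), BMP6 (1.42), GPNMB (1.27), MAF (1.19), ISG20 (1.03) and ZP4 (1.03).

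In this test 190 genes had a lower and 146 a higher response in the double knockdown, 63 and 10 of them by at least 2-fold. Without 1 array, whichever of the 8 it was, 51 to 115 were lower and 15 to 38 higher. Among genes above the median level 399 were lower and 565 higher, and with a variance prior that follows the level 450 and 491, so the balance turned. Counting each control array once, because the controls of the sets deviated together, gave 551 lower and 626 higher. All 336 genes of the first count were among these 1177. That fit keeps the fold changes and leaves out the error of the shift between sets, which lowers the SE. The overlap is therefore no separate support. The fit on 8 arrays in turn takes the controls of the sets as independent. Deviations that both control groups share cancel in the difference, so its SE there may be too large. The call of KRTDAP was lost without replicate 1 (adjusted p = 0.056) or replicate 2 (adjusted p = 0.054) of the EXOSC9 knockdown, and those of BMP6 without 3 of the arrays in turn (adjusted p between 0.055 and 0.069) and MAF without 7 of them (adjusted p between 0.053 and 0.094). Of the 62 named genes called in this test, 30 kept the call whichever array was left out. Of 31 of them with several probe sets, 19 had one with less than 50% of the difference given, 9 of them in the opposite direction, with differences between -2.91 and -0.06 for HOPX, -2.45 and -0.62 for S100A8, -0.13 and 1.83 for POSTN, 0.12 and 1.71 for SPP1, -0.22 and 1.42 for BMP6 and -0.16 and 1.19 for MAF. The difference for ZNF750 did not pass, at -1.37 (SE 0.42, limma adjusted p = 0.21). It passed with each control array counted once (limma adjusted p = 0.035), on the lowered SE of that fit, and its control levels were dim in both sets.

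By list, 21 of 45 cornified envelope genes had a lower response in the double knockdown and none a higher one, 29 when adjusted over the list alone, with a median of -0.55 (camera adjusted p = 6.61e-32, and adjusted p = 0.00255 with an estimated correlation). For spinous genes it was 12 of 35 and none higher (16 lower and 2 higher adjusted over the list alone, median -0.17, camera adjusted p = 2.35e-11, and adjusted p = 0.0273 with an estimated correlation), among them S100A9 (-2.67), S100A8 (-2.45) and DSG1 (-2.22). Histone genes were lower in 4 of 10, and 7 adjusted over the list alone (median -0.50, camera adjusted p = 2.09e-09, and adjusted p = 0.0455 with an estimated correlation) with H2BC21 at -1.63. Cholesterol synthesis genes were lower in 3 of 21, and 10 adjusted over the list alone (median -0.22, camera adjusted p = 6.12e-10, and adjusted p = 0.0273 with an estimated correlation) with ACSS2 at -0.60, a call lost without 6 of the 8 arrays in turn (adjusted p between 0.052 and 0.064). Cell cycle genes fell somewhat further in the double knockdown (median difference -0.21, 3 of 52 called and 14 adjusted over the list alone, camera adjusted p = 1.52e-15, and adjusted p = 0.0273 with an estimated correlation). Interferon genes were higher in 9 of 53 and lower in none, 26 adjusted over the list alone (median 0.23, camera adjusted p = 1.52e-15, and adjusted p = 0.0352 with an estimated correlation), with IFIT2 at 0.73, a call lost without 7 of the arrays in turn (adjusted p between 0.063 and 0.15). The lists of lipid barrier genes (median -0.11, camera adjusted p = 0.00208), p53 targets (0.08, camera adjusted p = 0.0146) and differentiation transcription factors (-0.04, camera adjusted p = 0.0443) passed as well, with adjusted p = 0.0828, 0.085 and 0.495 with an estimated correlation. The list of transcription factors holds GRHL3, the target of the siRNA, and without it did not pass (median -0.01, camera adjusted p = 0.159), a test added after the data were seen. Its call was also lost with each control array counted once (adjusted p = 0.0776), and without replicate 2 of the first controls (adjusted p = 0.136), replicate 1 of the EXOSC9 knockdown (adjusted p = 0.235), replicate 1 of the second controls (adjusted p = 0.2) or replicate 2 of the double knockdown (adjusted p = 0.0522). The other 10 lists did not pass camera for the difference, the closest being immune and endothelial markers (median -0.08, camera adjusted p = 0.149). Median and mean of the difference had opposite signs for the exosome (0.01 and -0.01), matrix (-0.02 and 0.08) and fibroblast (-0.06 and 0.05) lists.

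Across all 19775 genes the responses to the single and the double knockdown were correlated. Their log2 changes gave Pearson's r = 0.68 and Spearman's rho = 0.61, where genes are not independent replicates. Unchanged groups set against controls that deviate together as strongly as these did gave r = 0.39 in 100 simulated draws. The covariance was 0.0437 against 0.0027 in the simulation, a difference of 0.041. Both knockdowns raised 952 genes, where independent lists of these sizes would share 155.6. Both lowered 1185, where such lists would share 183.7. The simulation with no effect gave 0 in each direction. That follows from the adjustment of p, which leaves few calls where no gene changes, and it gives no baseline for these overlaps. Opposite calls numbered 29 for genes up in the EXOSC9 knockdown and 16 for genes down. Without 1 array, whichever it was, the shared calls numbered 432 to 797 up and 625 to 991 down. The controls could not be split with 2 arrays left in each part, so part of the excess may come from the shared controls.

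The genes that rose most on EXOSC9 knockdown had a smaller median rise with the GRHL3 siRNA. Of the 121 genes that rose at least 2-fold, with a median of 1.41, the median in the double knockdown was 0.65, and 71 still rose, 10 fell and 40 were not called. The difference itself passed in the direction of a smaller response for 61 of them. The 23 genes that fell at least 2-fold had a median of -1.07 and of -1.25 in the double knockdown, where all 23 fell. Over all calls, the 1341 genes that rose had medians of 0.35 and 0.33, and 952 rose, 29 fell and 360 were not called in the double knockdown, with 104 passing the test for a smaller and 31 for a larger response. The 1718 that fell had medians of -0.33 and -0.31, with 1185 again down, 16 up and 517 not called, and 40 passed the test for a smaller and 43 for a larger response. Without replicate 1 or 2 of the first controls, or replicate 2 of the EXOSC9 knockdown, fewer genes were selected and the second of these medians was -0.54, -0.50 and -0.49. The selection used 2 arrays that also enter the EXOSC9 change, so genes were also picked on one replicate pair and measured in the other. For the 121 largest rises the held-out medians were 1.45 in the EXOSC9 knockdown and 0.67 in the double knockdown, and for all 1341 rises 0.33 and 0.27.

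**Figure D3:**
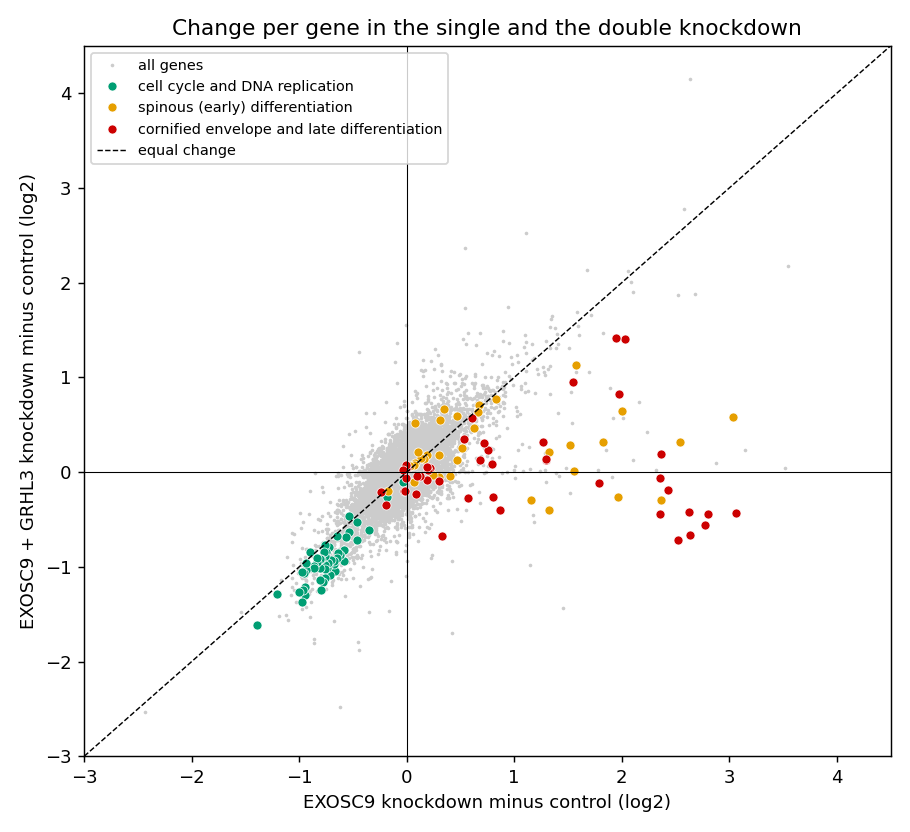
Change of each gene in the EXOSC9 knockdown (x axis, log2) against its change in the double knockdown (y axis, log2), each against its own controls, with all genes in grey, 3 lists in colour and a dashed line of equal change. Cell cycle genes (median -0.76 and -0.95) lie near the line and cornified envelope genes (median 0.72 and -0.05) lie mostly to the right of it.

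The controls of the sets, which have the same description, were compared to see how far the sets differ apart from the knockdowns. Levels in the second controls differed from those in the first by a median of -0.11, and 1719 genes were called lower and 125 higher, with few large changes. The largest were those of dim genes, such as C8orf74 (1.08), ZNF483 (0.79), SPATA25 (0.75), ZRANB2-AS1 (0.70) and GAPLINC (0.70) among the higher, and CSF1R (-1.08), LINC01858 (-1.07), ODAD3 (-1.06), ERICH4 (-1.04) and SHISA9 (-1.02) among the lower, each with a level below the gene median of 6.62 in both control groups. After centring the arrays on a common median 196 were lower and 256 higher, and after quantile normalization over all arrays 229 and 220. The test took the control groups as independent, so where they deviate together its SE may be too large. Without 1 of the 4 control arrays, whichever it was, 55 to 196 were lower and 3 to 11 higher. Of these 10 calls 4 held whichever array was left out. The call of ZRANB2-AS1 was lost without any of the 4 arrays (adjusted p between 0.077 and 0.16), and those of SPATA25 (0.053 to 0.057) and SHISA9 (0.053 to 0.056) were lost without replicate 2 of the first or either of the second controls. GAPLINC (0.055 and 0.051) and ERICH4 (0.071 and 0.064) lost theirs without replicate 2 of the first or replicate 1 of the second controls, and C8orf74 (0.05) without the latter.

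The control arrays of the sets deviated together more than those of any other pair of groups. Over 54613 probe sets the difference between control replicates 1 and 2 in the first set correlated with that in the second at r = 0.775, and at 0.743 in the 18205 dimmest probe sets, against 0.017 for the controls and knockdown arrays of the first set and 0.098 for those of the second. Between the knockdown groups it was 0.083, but 0.351 in the brightest 18204 probe sets. Between the double knockdown and the first and second controls it reached 0.135 and 0.132 in the probe sets of middle level. Same-numbered controls of the sets differed with an SD of 0.17 and differently numbered ones with SDs of 0.214 and 0.215. The replicates within a control group differed by less, with SDs of 0.148 and 0.147. In a further fit the controls of both sets were counted as 1 pair of control arrays, a choice made after the data were seen. On that count 1116 genes rose and 1388 fell in the EXOSC9 knockdown and 2082 rose and 1860 fell in the double knockdown, with unchanged fold changes, and 2468 and 3887 of these calls were among the 3059 and 4408 calls made with 8 arrays.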

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

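The tests on the control arrays and on the strength of the knockdown in this part were chosen after the results they concern had been seen. Genes and lists are given here because their change differed between the double and the EXOSC9 knockdown by the limma or camera test of the difference itself. Values are differences of log2 changes, double minus single. An effect of the GRHL3 siRNA by itself cannot be told from a changed response to EXOSC9 loss, as no group holds that siRNA alone. The test called 146 genes higher and 190 lower. By list, the median difference was -0.55 for cornified envelope genes, -0.17 for spinous genes, -0.21 for cell cycle genes, 0.23 for interferon genes, -0.22 for cholesterol synthesis genes and -0.50 for histone genes.

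Differentiation genes with a lower response were KRTDAP (-3.49), CRCT1 (-3.34), LCE3D (-3.30), SBSN (-3.25), PI3 (-3.24), IVL (-3.05), HOPX (-2.91), SERPINB3 (-2.80), S100A9 (-2.67), S100A8 (-2.45), DSG1 (-2.22), SDR9C7 (-1.46), GRHL1 (-1.42), S100P (-1.35), SPRR1B (-1.15), ELOVL7 (-0.81), SPRR3 (-0.62), KLK11 (-0.59) and CLDN1 (-0.45). GRHL3 itself, the target of the siRNA, differed by -1.96. Other genes with a lower response were SLC6A14 (-3.47), CLIC3 (-2.89), SLPI (-2.78), VGLL1 (-2.12), GJA5 (-1.86), IL36RN (-1.76), H2BC21 (-1.63), CXCL5 (-1.43), CXCL3 (-1.34), COL8A1 (-0.93), CCN2 (-0.90), AGR2 (-0.89), H2AC6 (-0.83), SPINK6 (-0.80), DUSP1 (-0.70), CCN1 (-0.69), ACSS2 (-0.60), EBP (-0.50), HMGCS1 (-0.49), HSP90B1 (-0.46), EPCAM (-0.43), AURKB (-0.40), MFAP5 (-0.39) and PDIA4 (-0.38). Those with a higher response were POSTN (1.83), SPP1 (1.71), LOC100130331 (1.57), CCL27 (1.52), SLITRK6 (1.46), BMP6 (1.42), MAF (1.19), GPNMB (1.27), ISG20 (1.03), ZP4 (1.03), MMP10 (0.88), TGFBI (0.84), KRT15 (0.80), IFIT2 (0.73), HBEGF (0.72), CMPK2 (0.45), TP53INP1 (0.44) and OAS2 (0.41). Of the 62 named genes called, 30 kept the call whichever of the 8 arrays was left out. The calls of AURKB, CLDN1, CMPK2, EBP, EPCAM, HMGCS1, KLK11, MFAP5, OAS2, PDIA4 and TP53INP1 were lost without any of them.

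Probe sets without a gene symbol are used in no comparison of named genes, and a signal appeared there too: of 11721, 257 were called up and 141 down in the EXOSC9 knockdown, and 490 up and 248 down in the double knockdown. The shares called up were 2.19% and 4.18%, against 1341 and 2294 of the 19775 named genes. The named genes come from a separate fit, each by its brightest probe set, so these shares are not measured alike.

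The first pattern is that part of the differentiation genes, most of the cornified envelope list among them, did not rise with the second siRNA while cell cycle genes still fell; 13 of 35 spinous genes and 71 of the 121 largest rises were still called up. A weaker EXOSC9 knockdown in the second set would shrink both, but the cell cycle median there was 1.25 times that of the first set, and EXOSC9 fell as far. For the 121 largest rises, noise in the arrays used to select them is also argued against. Genes chosen on one replicate pair rose in the other by 0.79 more in the EXOSC9 than in the double knockdown (0.71 and 0.86 for the 2 choices of the pair). Over all 1341 rises the gap was 0.05 (0.02 and 0.09). Picking genes by a large EXOSC9 response can by itself leave a smaller double response. The reverse choice, by the double response, was not made, so this part of the selection stays open. Whether the GRHL3 siRNA acted through other targets cannot be told apart from loss of GRHL3, since 0 groups hold the GRHL3 siRNA without the EXOSC9 shRNA, or another GRHL3 siRNA. A need for GRHL3 in the rise of the genes that lost it is one hypothesis that stays open beside that one.

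The second pattern is the joint deviation of the control arrays. Summarising the same 2 hybridizations in 2 runs of RMA is a candidate explanation: the replicate differences of the control groups correlated at 0.743 even in the 18205 dimmest probe sets, where separate hybridizations would share little. Same-numbered controls still differed more between the sets (SD 0.17) than replicates within a control group (0.148 and 0.147). How much of that separate processing would add was not tested. Culture batches that follow the replicate numbers are argued against as the whole cause of the controls' 0.775, since the higher of the correlations between controls and their own knockdown arrays was 0.098. A smaller component shared by replicate number stays open, as the knockdown groups correlated at 0.351 in the brightest probe sets and the double knockdown with the controls at 0.132 and 0.135 in those of middle level. No biological explanation was tested for this pattern, and the raw scans were not used here.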

How the results depend on the processing

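The fit with each control array counted once, the transcription factor list without GRHL3 and the tests of named genes in contrasts for which the rule did not name them and the split of the controls for noncoding genes were added after the data were seen, and the other alternatives were planned. Of the tests on named genes under the alternatives, 3971 kept direction and call, 772 kept the direction and lost the call, 1 gained it and 0 reversed. Leaving out 1 array accounted for 357 of the lost calls. For the gene lists 770 kept both, 34 lost and 12 gained the call, and 1 reversed: the cornified envelope list in the double knockdown (median -0.05) was called up by fry (adjusted p = 0.0073), while camera gave an adjusted p of 0.797, and the cause was not tested. RMA values carry no background level per probe, so signal over background limits changes of dim genes to an unknown extent.

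Without 1 array, 600 to 674 genes rose and 726 to 901 fell in the EXOSC9 knockdown, 1187 to 1686 and 1198 to 1637 in the double knockdown, 15 to 38 and 51 to 115 for the difference and 3 to 11 and 55 to 196 between controls. Shared calls then ranged from 432 to 797 up and 625 to 991 down, the correlation from 0.63 to 0.67, the median double response of genes up in the EXOSC9 knockdown from 0.32 to 0.47 and of those down from -0.54 to -0.32. A group with 1 array was assumed to vary like the others, and fewer arrays alone lower these counts.

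With a 2-fold minimum, whether p was adjusted or not, 121 genes rose and 23 fell in the EXOSC9 knockdown and 94 and 113 in the double knockdown, and for the difference 10 and 63 with an adjusted p and 12 and 72 without. The medians of selected genes in the double knockdown were then 0.65 and -1.25. Pooling all control arrays gave 1635 rises and 1106 falls in the EXOSC9 knockdown, against 1341 and 1718, and 1577 and 2558 in the double knockdown, against 2294 and 2114, so the balance turned in both. The pooled controls mix sets whose levels differed by a median of -0.11, and fitting only the second set gave 1480 rises and 1372 falls in the double knockdown, with fewer degrees of freedom. Testing every probe set gave 3638 rises in the double knockdown, 44 higher and 125 lower for the difference and 343 and 4102 between controls. These are counts over 54613 probe sets and not over 19775 genes, so they are not measured alike. The mean of a gene's probe sets gave 87 higher for the difference and 2995 lower between controls. Beyond the number tested, the cause of these changes was not examined.

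Genes above the median level gave 565 higher and 399 lower for the difference, 5 and 889 between controls, and a correlation of 0.72. A variance prior with a trend gave 491 and 450 for the difference, where the cause was not tested either, and each control array counted once gave 626 and 551, from a smaller SE of that contrast. The direct contrast of the knockdowns, which includes the shift between the sets, called 909 higher and 5068 lower. Centring gave 256 higher and 196 lower between controls and quantile normalization 220 and 229, since both remove the shift of the median. With an estimated correlation 3 lists were called in the EXOSC9 and 3 in the double knockdown, against 12 and 7, and fry, which does not compare a list with other genes, called 11 in the double knockdown. In the EXOSC9 knockdown the estimate lay below the preset 0.01 for the cornified envelope (-0.007), p53 (-0.027), snoRNA host (-0.026) and matrix (0.004) lists. Their p weakened too, so correlation between genes is not the cause there.

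Replicate numbers were not taken to pair the samples, since the deviations of controls and knockdown arrays with the same number correlated at 0.017 and 0.098. Those of the control groups did correlate, at 0.775. With a term for the replicate number 158 genes were higher and 2397 lower between controls. With the replicate block, 13 genes were higher and 60 lower for the difference, 72 of them among the 336 without it, and 2065 of 3059 calls in the EXOSC9 and 3434 of 4408 in the double knockdown were shared with the fit without it. The robust prior was not run for lists, and the melanocyte list had no member above the median level.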

Other observations

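The tests in this part were set out after single noncoding transcripts had been seen among the largest rises, and before the counts over all of them were known, except the split of the controls, which was added later. Long noncoding RNA genes rose more often than they fell in both knockdowns. Of 2657 such genes 178 rose and 45 fell in the EXOSC9 knockdown, and 231 rose and 71 fell in the double knockdown, with 138 up and 9 down in both, where independent lists of these sizes would share 15.5 and 1.2. Their median changes were 0.02 and 0.00, and the others were not called. As the controls of the sets deviate together, how much of that overlap comes from them is unknown. With differently numbered control arrays for each knockdown, 1 per comparison, 67 or 74 were up in both, where independent lists would share 4.2 or 4.1. Chosen after their values were seen, as the 10 largest rises of the EXOSC9 knockdown called up in both, were DSP-AS1 (2.10 and 1.90), LINC01003 (1.71 and 1.66), ZEB1-AS1 (1.68 and 2.13), MIR200CHG (1.59 and 1.55), SNHG19 (1.59 and 1.69), HCG4 (1.40 and 1.36), LINC00938 (1.39 and 1.45), LINC00115 (1.38 and 1.31), LOC646903 (1.35 and 1.65) and ASH1L-AS1 (1.34 and 1.32), as log2 changes in the EXOSC9 and the double knockdown. The test of the difference called 1 long noncoding gene higher and 3 lower in the double knockdown, so for nearly all of them no effect of the GRHL3 siRNA passed.

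A hypothesis is that noncoding transcripts accumulate when EXOSC9 is depleted, since the exosome degrades many of them. The share called up minus the share called down was 5.01% of long noncoding genes in the EXOSC9 knockdown. Dim probe sets as the cause are argued against, since 1000 draws of protein-coding genes matched on level had a mean of 0.124% and an upper bound of 0.866%. A difference in normalization between the sets cannot be weighed this way, as a shift common to a set cancels against its own controls. The excesses of the EXOSC9 and the double knockdown were both past matched genes, in the double at 6.02% against an upper bound of 0.829%. These are not separate measurements while the controls are shared. With the controls split, the excess was 3.05% to 4.22%, against upper bounds of 0.414% to 0.979%. That argues against a chance deviation of only 1 control array as the cause. A deviation common to both control arrays stays in every split. The draws vary genes and not arrays, so that chance was not tested. Probe sets without a symbol showed a smaller excess, 0.99% against an upper bound of 0.256% for named probe sets of the same level in the EXOSC9 knockdown and 2.06% against 1.09% in the double knockdown, while the excess of 497 pseudogenes, 1.01% and 1.41%, lay inside the matched ranges. The pattern may be biological, but slower decay, more transcription and read-through from neighbouring genes were not told apart here.

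The change of many named genes rests on part of their probe sets, as those of PCF11 and HOPX do. The probe sets of PCF11 changed by between 0.00 and 2.06 in the EXOSC9 knockdown, and those of HOPX by between 0.02 and 3.15. For SPRR3 the probe sets went apart in the double knockdown, with 1.41 and -0.51, so its difference between the responses was -0.62 or -2.81. Those of POSTN (-0.29 to 2.37), BMP6 (0.04 to 2.53) and MAF (-0.16 to 1.73) also spread widely there. Which transcript ends they measure was not analysed here.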
